A study of Mus musculus with 12 samples.

How the data were processed

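Total RNA from mouse brown adipose tissue was measured on single-colour Illumina bead arrays. The 12 arrays form 4 groups of 3, from wild-type mice and mice labelled IL15 knockout, each on a normal diet or on a diet containing CL 316243, an agonist of the beta3-adrenergic receptor. Per the labels' protocols, RNA was extracted with Trizol, cleaned and treated with DNase I on RNeasy columns, checked on a Bioanalyser and turned into biotinylated cRNA with a MessageAmp kit. The dose, duration of the diet, age and sex of the mice are not given in the sources used here. The labels do not say that each array holds RNA from a separate animal, so every p-value and standard error measures the spread between arrays, and no chip or batch is given for any array.

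The deposited non-normalized table holds the intensity of each probe on a linear scale, summarised over its beads; the software and any background setting are not given in the sources used here. Beside each intensity the deposited table holds a detection p-value, per the file headers. A further table deposited by the authors holds log2 values that are normalized between arrays. RMA is the only tool that the submitters' processing notes name, with no role or version. In a check of the authors' log2 values against the intensities, each array's values matched its own intensity column best on 12 of 12 arrays. After each probe's mean was removed, the correlations with the own column were 0.913 to 0.991, and the highest with any other array was 0.581.

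The intensities were corrected for background, quantile normalized and put on the log2 scale with an offset of 16 by the neqc function of limma 3.58.1 in R 4.3.3, which inferred the background from the detection p-values. Of 45281 probes, 17502 (38.7%) had a detection p-value under 0.05 on at least 3 arrays and were tested. Of all probes, 34885 carried 1 gene symbol, 18 carried several and 10378 were not in the annotation of the array, which left them unnamed. Entrez identifiers of 34807 probes matched the reference gene table of assembly GRCm38.p6, which was used for names and chromosomes; no coordinates are given because the array annotation names no genome build. The tested probes with a symbol, 15083 in number, stood for 10150 genes, and each gene was represented by its probe with the highest mean over the 12 arrays.

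A linear model with 4 group means was fitted to all 12 arrays with limma, with moderated variances (8 residual and 4.94 prior degrees of freedom). The 7 comparisons were the effect of the CL diet in each genotype, the effect of genotype on each diet, the difference of the CL effect between genotypes, and the effects of diet and of genotype averaged over the other factor. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested probes within a comparison, with a threshold of 0.05; every adjusted p of a gene in the text comes from this limma fit. Log2 changes are CL minus normal diet or knockout minus wild type. Where a probe was not detected on any array of a group, its fold was computed against the detection floor of those arrays and is given as a lower bound. In simulated data with these arrays' variances and 17502 probes, a change of 1 log2 unit was recovered for 77% of changed probes for the CL effect in wild type and in knockout, 78% and 81% for the effect of genotype on the normal and CL diets, 30% for the difference of the CL effect, and 98% and 99% for the averaged effects of diet and genotype. A change of 2 log2 units was recovered for 95% of probes for the difference of the CL effect and for 98% to 100% in the other comparisons, and 2.22% to 5.35% of the calls were false.

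Before the data were examined, 22 gene lists were fixed: brown fat and thermogenic genes, cAMP-responsive early genes, lipolysis and lipid uptake, fatty acid oxidation, fatty acid and triglyceride synthesis, oxidative phosphorylation, glycolysis and glucose uptake, white adipocyte genes, unfolded protein response, interferon-stimulated genes, chemokines and inflammatory mediators, cell cycle genes, circadian clock genes, fibroblast and extracellular matrix genes, and markers of macrophages, NK and cytotoxic cells, T cells, B and plasma cells, skeletal muscle, endothelium, erythroid cells and Schwann cells or nerve. Each list was compared with all other genes by camera in limma with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the arrays. No list call in any comparison held with the estimated correlation. In simulated data for the CL effect in wild type, with 10150 genes, shifting the 17 macrophage markers by 0.5 log2 units gave an adjusted p of 6.79e-10, or 0.00211 with an estimated correlation, and 22 of 439 tests of unshifted lists had an unadjusted p under 0.05. The simulated genes varied independently, so these rates do not show that the preset correlation suits the real lists. On the arrays the estimated correlation was 0.271 for macrophage markers and 0.898 for skeletal muscle markers. List scores are the mean deviation of the members of a list from their 12-array means.

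Genes named in the text follow a rule fixed before the data were examined. For each comparison it takes the 8 largest folds in each direction among probes past the threshold, with no overlap between the 3 and 3 arrays of 2 compared groups, up to 4 members of each list that passed its test, and genes of interest that were always looked up: Il15, Il15ra, Il2rb, Ucp1, Dio2, Ppargc1a, Elovl3, Cidea, Adrb3, Lep, Adipoq, Fasn, Scd1 and Fgf21. For the CL diet in knockout, 1 gene that the rule takes is not reported here. Genes outside the rule are marked as chosen after their values were seen. For 3 against 3 arrays without any difference, 10% of probes show no overlap between the groups.

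The alternatives fixed before the data were examined were the authors' normalized values, no background correction, median scaling, no filter and a stricter filter on dim probes (detection p-value under 0.01 on all 12 arrays, leaving 10069 probes and 6542 genes), the replicate number as a block, array quality weights, trended and robust moderation, a fit of only the compared groups, the other probes of a gene and each array left out in turn. Numbers of alternatives and ranges of adjusted p in the text leave out the other probes of a gene, and for lists the estimated correlation, except where these are named. A fit with the mean of the skeletal muscle markers as a covariate, a fit without the 2 arrays richest in those markers and an adjustment without chromosome 1 were added after seeing the data. Chip as a block was planned and not run, since no chip is given. The same replicate numbers recur in the groups, but nothing in the labels says that a number marks a shared animal, litter or day, so the arrays were treated as unpaired. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3. The number of arrays, 3 per group, limits the precision of every value.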

Results

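Gene expression was measured in brown adipose tissue, the heat-producing fat of mice, on 12 Illumina arrays in 4 groups of 3: wild type on a normal diet, wild type on the CL diet, IL15 knockout on a normal diet and IL15 knockout on the CL diet. IL15 is a cytokine that sustains NK cells and other lymphocytes, and CL 316243, the compound in the CL diet, activates the beta3-adrenergic receptor, through which noradrenaline stimulates brown fat. The median probe intensity lay between 89.3 and 111 on the 12 arrays, and 31.1% to 35.8% of probes were detected on each. The first principal component of the normalized values held 29.3% of the variance and separated the diets, with all 6 normal-diet arrays on 1 side and all 6 CL arrays on the other. The second component held 16.4%.

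The targeted gene was examined first. Il15 was not lower on the arrays labelled IL15 knockout. The brightest of 3 tested Il15 probes had a mean log2 signal of 6.91 ± 0.22 in wild type and 7.97 ± 0.85 in knockout on the normal diet, and of 7.13 ± 0.19 and 7.24 ± 0.13 on the CL diet (SD, n = 3 arrays each). On the normal diet the 3 probes stood 1.06, 0.85 and 0.62 log2 units above wild type, with adjusted p of 0.505, 0.596 and 0.613, and on the CL diet 0.11, 0.26 and 0.33 above it, all with an adjusted p of 0.999. Another pair of Il15 probes was detected on 0 arrays. The deleted part of the gene is not given in the sources used here, so probes outside it check nothing. These probes do not exclude wrong genotype labels either, a limit on every comparison of genotypes, for which the genotype is taken from the labels. Il2rb, which encodes a receptor subunit for IL15, was not detected on enough arrays to be tested, and no probe carried the name Adrb3, the beta3-adrenergic receptor.

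The beta3-adrenergic agonist changed many genes in wild-type tissue, while none of the 17 measured genes of the fixed brown fat and thermogenic list passed the test. Cyp2b10, a cytochrome P450 enzyme induced by many foreign compounds, rose most, by 4.16 ± 0.63 log2 units (SE), or 17.9-fold, from 6.37 ± 0.10 to 10.53 ± 1.11 (SD, n = 3 arrays per group, adjusted p = 0.00337). Depp1, a target of FoxO transcription factors, rose 8.37-fold (adjusted p = 0.0013). Trp53inp1, a p53-inducible gene linked to autophagy, rose 7.31-fold (adjusted p = 0.000279), and Gnmt, which methylates glycine, rose 5.02-fold (adjusted p = 8.84e-05). Histone genes of the H4 family stood among the largest increases, H4c8 at 8.34-fold, H4c1 at 7.45-fold and H4c11 at 6.57-fold. Their near-identical sequences leave open which copy a probe measures. Acot1, a cytosolic acyl-CoA thioesterase, fell 10.2-fold (log2 -3.35, adjusted p = 0.0254). Lcn2, a secreted acute-phase lipocalin, fell 6.00-fold (log2 -2.58, adjusted p = 0.0114). Hcar1, the lactate receptor of adipocytes, fell 4.41-fold (log2 -2.14, adjusted p = 0.000279).

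Among the other decreases, the glucuronosyltransferase Ugt1a10 fell 5.65-fold, Vat1l at least 5.25-fold, the chemokine Ccl7 4.66-fold, the extracellular protein Svep1 4.25-fold and Pmepa1, an inhibitor of TGF-beta signalling, 4.11-fold in wild type on the CL diet. Myoglobin (Mb) rose 6.61-fold (adjusted p = 0.0297) on arrays whose skeletal muscle marker scores ranged from -1.53 to 2.84 within the CL group. Mb was highest, at 10.95, on the CL array with the score of 2.84. It was still at 9.90 on the array with the score of -1.53. The wild-type normal-diet arrays, with scores of -0.88 to -0.16, had Mb at 7.16 to 7.69, so Mb did not simply follow the muscle score. Endothelial markers rose as a group in wild type (median log2 0.56, adjusted p = 0.000481; adjusted p = 0.733 with an estimated correlation). Of the 15 measured endothelial markers, 5 rose and 1 fell, or 8 and 1 adjusted over the list alone. Tie1, a receptor of vessel endothelium, rose 2.02-fold, the junction protein Esam 1.99-fold, the guidance receptor Robo4 1.90-fold and Pecam1 1.75-fold. Il15ra, the IL15 receptor subunit that presents the cytokine, rose 2.09-fold (log2 1.06, adjusted p = 0.0463).

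The hallmark genes of thermogenic brown fat that were looked up and tested did not pass in wild type. The mean log2 signal of Ucp1, the mitochondrial uncoupling protein, was 14.05 ± 0.17 on the normal diet and 13.92 ± 0.21 on the CL diet (SD, n = 3 arrays each, log2 change -0.14, adjusted p = 0.667 in limma). These signals, and those of Cidea (up to 14.40) and Scd1 (up to 14.38), lay near the top of the range of the arrays, whose highest raw intensity was 18966 to 33020. Dio2, the deiodinase that activates thyroid hormone, stood at 0.13, the coactivator Ppargc1a at 0.54, the lipid droplet protein Cidea at -0.03 and the fatty acid elongase Elovl3 at 1.36 log2 units (adjusted p = 0.218). Lep was at 0.22, Adipoq at -0.28, Fasn at 0.08, Scd1 at 0.19 and Fgf21 at -0.43 log2 units, with adjusted p of 0.346 to 0.912 for these genes. Dio2 (4.66 to 5.77) and Fgf21 (4.61 to 5.97) lay near the floor of the wild-type arrays, whose lowest detected values were 4.67 to 4.87. Their small changes therefore say little. Of the 17 brown fat and thermogenic genes measured, 0 passed, and 0 adjusted over the list alone. The whole comparison held 3661 probes with an unadjusted p under 0.05 in limma.

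**Figure D1:**
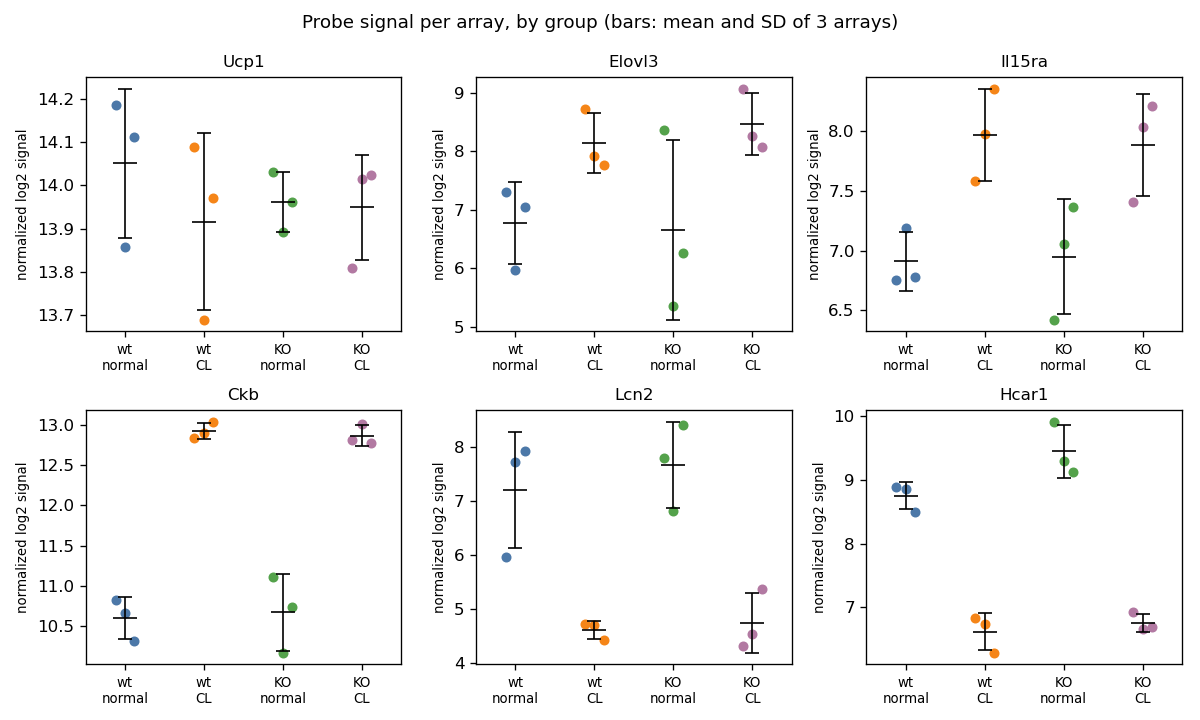
Normalized log2 signal of Ucp1, Elovl3, Il15ra, Ckb, Lcn2 and Hcar1 on each of the 12 arrays, by group; points are arrays, bars the mean and SD of 3 arrays. Ckb lies at group means of 10.60 and 10.67 on the normal diet and of 12.93 and 12.87 on the CL diet, whereas all 4 group means of Ucp1 lie between 13.92 and 14.05.

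In all, limma called 827 probes for the CL diet in wild type, 428 higher and 399 lower, standing for 627 named genes, and 267 of these probes changed by more than 2-fold. The balance of directions depends on the normalization: with median scaling 21.2% of 571 calls were higher, against 51.8% here. Called genes were more frequent than expected on chromosome 1 (43 of 509, 26.7 expected) and chromosome 13 (31, 17.2 expected), each with an adjusted p of 0.0213 in Fisher's exact test. That test takes genes as independent, whereas 18 histone genes with near-identical sequences were among the calls. The normal-diet arrays of wild type, 1 side of this comparison, had lower signals than every other array for 20 of 39 measured histone genes. Leaving out wild-type normal-diet array 1, 2 or 3 gave 364, 322 or 289 probes, leaving out wild-type CL array 2 or 3 gave 307 or 273, and leaving out the 2 arrays richest in muscle markers gave 287. Of the 21 named genes that passed, 11 kept their call under all alternatives run, other probes included, and that on Cyp2b10 ended with its other probe alone (0.30). Calls on Mb, Acot1, Lcn2, Ccl7, Il15ra and the 4 endothelial markers ended under some. Leaving out any of the 6 arrays ended at least 1 of these calls, with adjusted p of 0.00231 to 0.342 over their alternatives.

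In IL15 knockout tissue the agonist diet also raised Cyp2b10, by 6.14-fold (log2 2.62 ± 0.63 SE, adjusted p = 0.043), a call that ended under 15 of 18 alternatives, with adjusted p of 0.0325 to 0.194. Firmer increases were those of Ckb, the brain-type creatine kinase, 4.58-fold from 10.67 ± 0.48 to 12.87 ± 0.13 (SD, n = 3 arrays per group, adjusted p = 0.000291), Gnmt at 4.31-fold, the BMP modulator Kcp at 3.88-fold and the calcium-binding protein Tesc at 3.69-fold. Rgs2 and Rgs3, which shorten G protein signals, rose 4.16-fold and 3.68-fold. Hcar1 fell 6.48-fold (log2 -2.70, adjusted p = 7.75e-05) and Igf1, the insulin-like growth factor, 5.29-fold (log2 -2.40, adjusted p = 0.000133). Lcn2 fell 7.60-fold, the protease inhibitor Serpina3n 7.34-fold, Ccl7 6.32-fold and the complement component C2 5.27-fold.

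Inflammatory gene groups fell together in knockout tissue on the CL diet. Chemokines and inflammatory mediators fell (median log2 -0.83, adjusted p = 0.000163; adjusted p = 0.335 with an estimated correlation), a call that ended with the stricter filter on dim probes (adjusted p 1.34e-05 to 0.19 over all alternatives). Of the 15 measured, 4 fell, or 8 adjusted over the list alone, among them Cxcl14 at log2 -1.07 and Ccl9 at -1.81. In wild type the chemokine list narrowly missed the threshold in the same direction (median -0.46, adjusted p = 0.0653 in camera), so its fall is not particular to knockout. Interferon-stimulated genes fell (median -0.53, adjusted p = 0.00064; adjusted p = 0.404 with an estimated correlation), with 3 of 19 past the threshold and 6 adjusted over the list alone. These were Bst2, which tethers virus particles, at log2 -1.64, Oasl2 at -1.13 and the transcription factor Irf7 at -0.96. Macrophage markers fell as a group (median -0.59, adjusted p = 0.000163; adjusted p = 0.335 with an estimated correlation), although 0 of 17 members passed, or 2 adjusted over the list alone. Fcer1g stood at -0.86, Cd14 at -1.07, Mrc1 at -0.84 and Adgre1 at -0.72 log2 units. The knockout normal-diet arrays are 1 side of this comparison and also of that of genotypes on the normal diet. High values on those arrays would give both a fall with CL here and a higher level in knockout there.

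Metabolic, clock and protein-folding groups changed too. Oxidative phosphorylation genes rose by a median of 0.09 log2 units (adjusted p = 0.0235; adjusted p = 0.335 with an estimated correlation), with 1 of 22 past the threshold, or 2 adjusted over the list alone. That gene was Sdhb, a subunit of complex II, at 0.69, while another Sdhb probe stood at -0.02. Glycolysis and glucose uptake genes rose by a median of 0.22 (adjusted p = 0.0337; adjusted p = 0.335 with an estimated correlation), with 0 of 14 past the threshold, and Slc2a1, the GLUT1 transporter, was at 0.68 log2 units. Their median in wild type was much alike, at 0.24, and narrowly missed the threshold (adjusted p = 0.0653 in camera). Endothelial markers rose by a median of 0.22 (adjusted p = 0.0198; adjusted p = 0.404 with an estimated correlation), 3 of 15 higher and 1 lower, or 5 and 1 adjusted over the list alone, with Tie1 at 1.03, Robo4 at 0.89 and Esam at 0.76. Circadian clock genes fell (median -0.44, adjusted p = 0.0193; adjusted p = 0.335 with an estimated correlation), 2 of 12 past the threshold, or 4 adjusted over the list alone, these being Per3 at -1.14 and the clock output factor Dbp at -2.20. Genes of the unfolded protein response fell on balance (median -0.55, adjusted p = 0.035; adjusted p = 0.335 with an estimated correlation), with 2 higher and 5 lower of 15, or 4 and 8 adjusted over the list alone. The chaperones Dnajb9, Pdia4, Sdf2l1 and Calr were at -0.92, -0.91, -0.86 and -0.73.

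Skeletal muscle markers fell most, by a median log2 of -3.54 (adjusted p = 1.36e-08; adjusted p = 0.335 with an estimated correlation), with 1 of 14 past the threshold, or 13 adjusted over the list alone. Tcap and Csrp3, both proteins of the muscle Z-disc, were at -3.98 and -3.96, and their calls each ended under 12 alternatives. The mean muscle marker score was 1.58 ± 1.38 in knockout on the normal diet, with single arrays from 0.39 to 3.10, and -1.48 ± 0.80 on the CL diet (SD, n = 3 arrays each), so the amount of muscle transcript differed between the arrays compared. Elovl3 was at 1.81 (adjusted p = 0.125), Il15ra at 0.94 (adjusted p = 0.0872) and Ucp1 at -0.01 log2 units (adjusted p = 0.978).

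For the CL diet in knockout, limma called 529 probes, 294 higher and 235 lower, standing for 401 named genes, and 206 of them changed by more than 2-fold. With median scaling 23.4% of 167 calls were higher, against 55.6% here. With the muscle marker mean as a covariate 33 probes were called, and without knockout normal-diet array 1 or knockout CL array 1 or 2 there were 180, 210 or 163. Of 31 named genes past the threshold, 6 kept their call under all alternatives, other probes included: Ckb, Rgs2, Kcp, Tesc, Hcar1 and Igf1. That on Gnmt ended with its other probe alone (0.82). Leaving out any of the 6 arrays ended at least 1 of the other calls, with adjusted p of 0.000514 to 0.425 over their alternatives. Among the lists, those of macrophage markers and interferon-stimulated genes kept theirs under all alternatives except the estimated correlation, at medians of -0.77 to -0.16 and of -0.82 to -0.21, both nearest to 0 with the authors' values. Without knockout normal-diet array 1, 2 or 3 or knockout CL array 3, at least 1 of the oxidative phosphorylation, glycolysis, endothelial, circadian and protein-folding calls ended, with adjusted p of 7.75e-06 to 0.344 over the alternatives of these lists. The muscle covariate ended the oxidative phosphorylation, circadian and protein-folding calls and that on muscle markers (up to 0.91), and leaving out the 2 muscle-rich arrays ended the endothelial and circadian calls. The stricter filter ended the oxidative phosphorylation, glycolysis, circadian and protein-folding calls, median scaling the glycolysis call, and the lack of background correction the protein-folding call. Medians that moved by over 1.5 times were those of macrophage markers without knockout normal-diet array 1 (-0.39), interferon-stimulated genes without knockout CL array 1 (-0.82), endothelial markers without knockout normal-diet array 3 (0.46) or knockout CL array 1 (0.37), glycolysis genes without knockout normal-diet array 2 (0.36) and oxidative phosphorylation genes without knockout CL array 1 (0.16).

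The responses of the 2 genotypes to the diet ran in the same direction. The comparisons use different arrays, and 146 probes were called higher in both (7.19 expected for independent lists) and 95 lower in both (5.36 expected), with 0 called in opposite directions, among 1115 called in either. Of the probes called in wild type, 96.5% had the same sign in knockout, and of those called in knockout, 98.1% had the same sign in wild type. Across all tested probes, which are not independent replicates, the log2 changes correlated at r = 0.469.

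**Figure D2:**
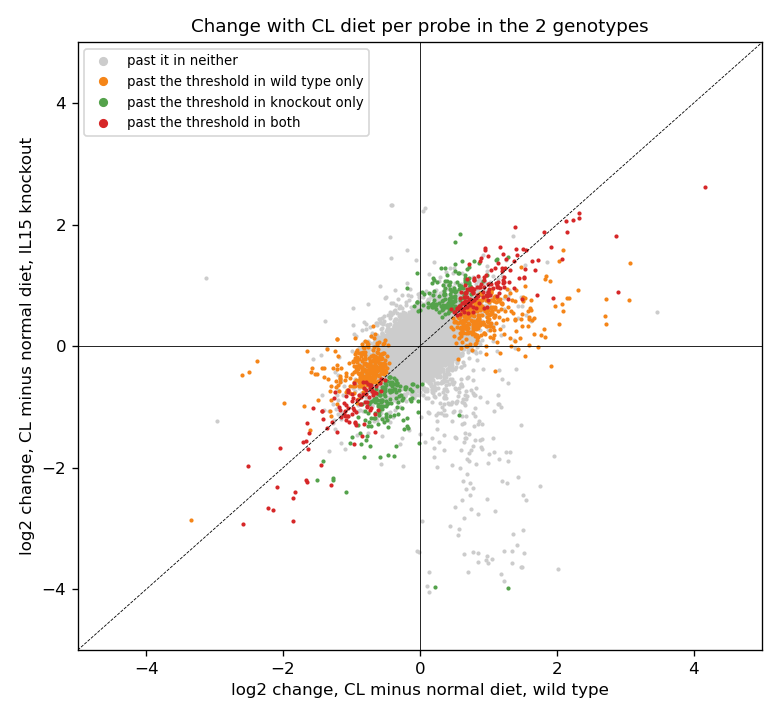
Log2 change with the CL diet per tested probe in wild type (horizontal axis) and in IL15 knockout (vertical axis), coloured by whether the probe passed the threshold in both genotypes, in 1 or in neither; the dashed line marks equal change. The 146 probes called higher in both and the 95 called lower in both lie in the quadrants of equal sign.

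Few genes differed between genotypes on the normal diet, and those gathered on chromosomes 1 and 13. Insig2, an endoplasmic reticulum protein that restrains sterol synthesis, was 5.13-fold higher in knockout, at 8.38 ± 0.13 against 6.03 ± 0.42 in wild type (SD, n = 3 arrays each, log2 2.36 ± 0.20 SE, adjusted p = 0.000176), while another Insig2 probe differed by 0.23. Wdfy1, which encodes an endosomal protein, was 6.80-fold lower, at 5.67 ± 0.14 against 8.43 ± 0.07 (log2 -2.77 ± 0.19 SE, adjusted p = 2.93e-05), with another probe at -0.33. Ugt1a10 was 4.25-fold lower (log2 -2.09, adjusted p = 0.000768) and Cat, the peroxisomal catalase, 3.23-fold higher (log2 1.69, adjusted p = 0.00246). Ugt1a6b was 3.02-fold, the chitinase-like Chil1 2.63-fold and Lypd1 2.32-fold lower, and the receptor Lgr6 3.20-fold higher. Histone H4 probes were higher in knockout, H4c8 5.05-fold, H4c11 3.90-fold, H4c1 3.87-fold, H4c18 3.43-fold and H4c12 2.73-fold.

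Of the 21 called genes with a chromosome, 9 lay on chromosome 1 (1.10 expected, adjusted p = 4.91e-06, Fisher's exact test) and 8 on chromosome 13 (0.709 expected, adjusted p = 4.54e-06), where histone clusters lie. Fisher's exact test takes genes as independent. Of the called genes, 10 were histone genes, whose near-identical probes can move together, so the p for chromosome 13 does not measure chance for separate genes. For 8 of the 9 chromosome 1 genes, the wild-type CL mean lay nearer to the knockout than to the wild-type mean of the normal diet. Insig2, for example, stood at 7.94 in wild type on CL, and Ugt1a10 at 7.38. Wdfy1 was the exception, at 8.04 in wild type on CL. This comparison and that of the diets in wild type share the wild-type normal-diet arrays. Of the called probes, 18 were higher in both (0.611 expected for independent lists) and 6 lower in both (0.182 expected). In 50 simulated draws with shared arrays but no difference between groups, a mean of 0.04 probes was shared. Such draws give few calls by design, so they do not show how much overlap the shared arrays add where groups differ. The r across probes was 0.324, against 0.497 in those draws. The 3 shared arrays are too few to be divided between the comparisons.

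Marker lists of macrophages and matrix were higher in knockout tissue on the normal diet, with no single gene of these lists past the threshold. All 17 macrophage markers were above wild type (median log2 0.67, adjusted p = 7.31e-11; adjusted p = 0.241 with an estimated correlation). Over all probes 0 passed, and 6 adjusted over the list alone. The values of 4 members were Lyz2 at 1.36 and Lyz1 at 1.08, and the complement chains C1qa at 1.18 and C1qb at 0.95. Fibroblast and extracellular matrix genes were higher (median 0.39, adjusted p = 2.98e-06; adjusted p = 0.241 with an estimated correlation), and 0 of 17 passed, with Col5a1 at 0.46 and the basement membrane collagens Col4a1 and Col4a2 both at 0.39. Interferon-stimulated genes were higher (median 0.30, adjusted p = 1.09e-05; adjusted p = 0.46 with an estimated correlation), Bst2 at 0.82 and Oasl2 at 0.73, and 0 of 19 passed. Skeletal muscle markers were higher too (median 2.14, adjusted p = 6.56e-10; adjusted p = 0.46 with an estimated correlation), Acta1 at 2.81 and Ckm at 2.79, and 0 of 14 passed. Smaller list differences were those of chemokines (median 0.21, adjusted p = 0.017), cell cycle genes (median 0.14, adjusted p = 0.0284) and the unfolded protein response (median 0.08, adjusted p = 0.0498), with adjusted p of 0.529, 0.547 and 0.241 with an estimated correlation. In these lists 0 members passed, and adjusted over the list alone 1 unfolded protein response gene did. The list differences between genotypes on the normal diet and the falls with CL in knockout share the knockout normal-diet arrays, so they are not separate findings.

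**Figure D3:**
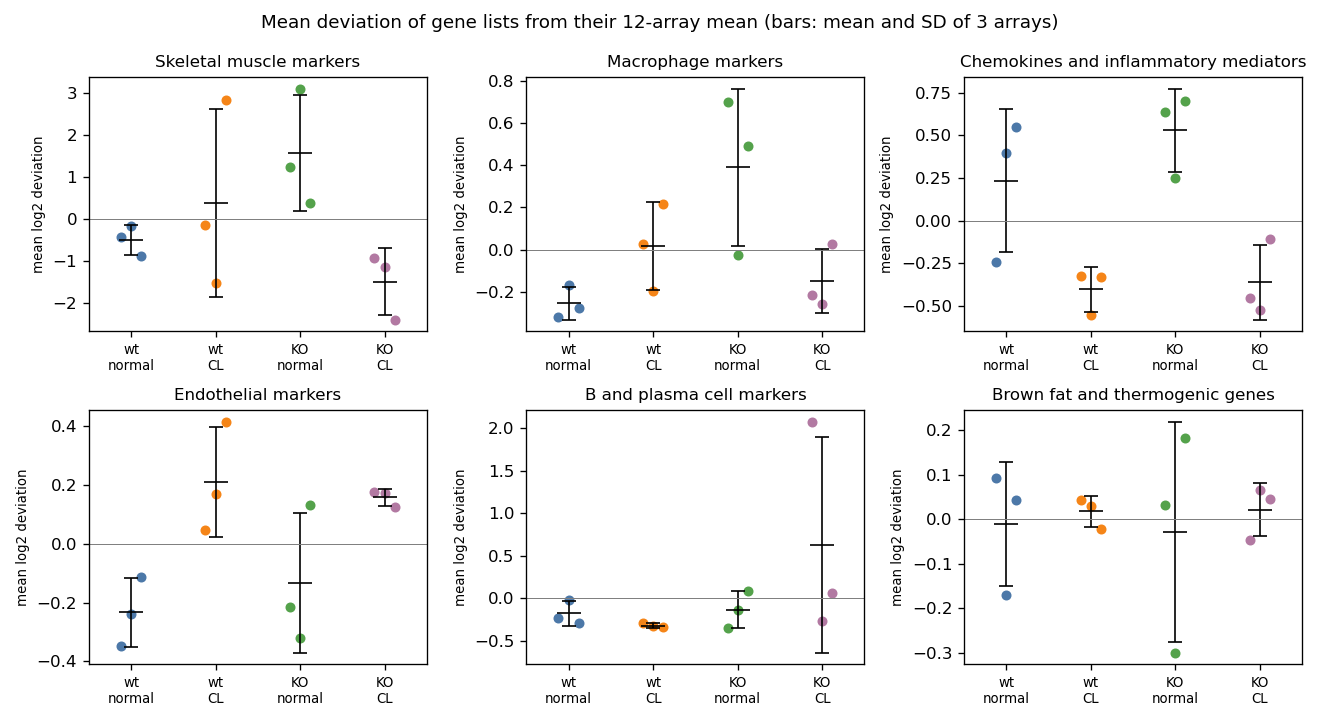
Mean log2 deviation of the members of 6 gene lists from their 12-array mean on each array, by group; bars are the mean and SD of 3 arrays. Skeletal muscle markers reach 3.10 on an array of knockout on the normal diet and 2.84 on an array of wild type on CL, and B and plasma cell markers reach 2.08 on a single array of knockout on CL.

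NK cell and cytotoxic lymphocyte markers, the cells most dependent on IL15, were barely measurable: 5 of the list were detected, 0 passed in any comparison, and the list test gave adjusted p of 0.847 and 0.659 for genotype on the normal and CL diets. T cell markers, 8 of them measured, gave adjusted p of 0.998 and 0.119. Ucp1 differed between genotypes by -0.09 log2 units on the normal diet and 0.03 on the CL diet, Elovl3 by -0.12 and 0.32 and Il15ra by 0.04 and -0.09.

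On the normal diet, limma called 33 probes for genotype, 25 higher and 8 lower, standing for 27 named genes. Without the 2 muscle-rich arrays 8 probes were called, with the muscle covariate 8, and with wild-type normal-diet array 1, 2 or 3 or knockout normal-diet array 1 or 2 left out 16, 13, 16, 11 or 13. Of 13 named genes, 3 kept their call under all alternatives, other probes included: H4c1, Cat and Ugt1a10. Those on Insig2 and Wdfy1 ended with their other probes alone (0.23 and -0.33). Calls on H4c8, Lgr6, H4c12, Ugt1a6b, Chil1 and Lypd1 ended with at least 1 of the 6 arrays left out, at adjusted p of 0.00105 to 0.256 over their alternatives. That on H4c18 ended with the authors' values, without background correction, with median scaling, without a filter, without the 2 muscle-rich arrays and with the muscle covariate (0.00165 to 0.352), and that on H4c11 in the fit of only the compared groups (0.000186 to 0.0534). The macrophage and matrix lists kept theirs except with the estimated correlation. The interferon call ended without wild-type normal-diet array 1, at an adjusted p of 0.108 (5.29e-12 to 0.108 over all alternatives). The chemokine call ended without wild-type normal-diet array 1 or knockout normal-diet array 1 or 3, the cell cycle call without wild-type normal-diet array 1 or knockout normal-diet array 3, and the unfolded protein response call with any of the 6 arrays left out except wild-type normal-diet array 2, with adjusted p of up to 0.799, 0.522 and 0.251 over their alternatives. The stricter filter ended these 3 calls as well. The cell cycle call also ended with the authors' values, the cell cycle and unfolded protein response calls without background correction, the latter also with array weights, and the muscle covariate ended the calls on the unfolded protein response and muscle markers (0.834 for muscle).

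For genotype on the normal diet, the list medians that moved by over 1.5 times with 1 array left out were these. The macrophage median was 0.44 without knockout normal-diet array 1 and the muscle median 1.30 without knockout normal-diet array 2. The interferon median was 0.07 or 0.48 without wild-type normal-diet array 1 or 3 and 0.47 without knockout normal-diet array 1. The chemokine median was 0.07 or 0.38 without wild-type normal-diet array 1 or 3, and 0.13 or 0.33 without knockout normal-diet array 1 or 2. The cell cycle median was 0.29 or 0.01 without knockout normal-diet array 2 or 3. The unfolded protein response median was 0.13 without wild-type normal-diet array 1, and 0.14, 0.13 or 0.15 without knockout normal-diet array 1, 2 or 3.

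On the CL diet the genotypes differed in Wdfy1 and little else. Wdfy1 was 4.45-fold lower in knockout, at 5.88 ± 0.44 against 8.04 ± 0.05 (SD, n = 3 arrays each, log2 -2.15 ± 0.19 SE, adjusted p = 0.000597), and the other of the 2 called probes, which was higher, carries no gene name. Circadian clock genes were lower (median -0.38, adjusted p = 0.000554; adjusted p = 0.483 with an estimated correlation), with 0 of 12 past the threshold, or 2 adjusted over the list alone, and Per1, Per2, Per3 and Tef at -0.97, -1.51, -0.61 and -0.69, while another Per2 probe was at 0.18. B and plasma cell markers were higher (median 1.15, adjusted p = 0.015; adjusted p = 0.515 with an estimated correlation), 0 of 4 past the threshold, or 1 adjusted over the list alone, with Cd79b, a chain of the B cell receptor complex, at 1.49 log2 units, and Fcmr, detected on 0 wild-type CL arrays, at least 2.45-fold higher. Their score was 2.08 on knockout CL array 1 and between -0.35 and 0.09 on the other 11 arrays. On that array the scores of T cell markers (1.08) and NK cell markers (0.54) were the highest of the 12 as well. Cell cycle genes were higher (median 0.24, adjusted p = 0.0126; adjusted p = 0.515 with an estimated correlation) and muscle markers lower (median -2.13, adjusted p = 1.65e-09; adjusted p = 0.515 with an estimated correlation), with 0 members of either past the threshold, or 0 cell cycle genes and 1 muscle marker adjusted over the list alone.

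At an unadjusted p under 0.05 the comparison of genotypes on CL held 618 probes. The call on Wdfy1 ended with its other probe (-0.13) and in the fit of only the compared groups, which called 0 probes (adjusted p 2.15e-05 to 0.0869 over all alternatives). Without knockout CL array 1 or wild-type CL array 1 the B cell call ended, without knockout CL array 1 or wild-type CL array 2 the cell cycle call, and without wild-type CL array 3 the circadian call, with adjusted p of up to 0.718, 0.41 and 0.192 over the alternatives of these lists. The muscle covariate ended these 3 calls and the muscle call (0.968). The B cell and cell cycle calls also ended with the authors' values, array weights or chromosome 1 left out, and the B cell call in the fit of only the compared groups. Without knockout CL array 1 the B cell and cell cycle medians were 0.23 and 0.09, and without wild-type CL array 3 the circadian and muscle medians were -0.17 and -0.71. The muscle median was -3.26 without wild-type CL array 2.

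Whether the genotype changes the response to the agonist was tested by the difference of the CL effects, knockout minus wild type. Limma called 3 probes for 2 genes, 901 probes having an unadjusted p under 0.05. Insig2 rose with CL in wild type, from 6.03 to 7.94, and stood at 8.38 and 8.06 in knockout. The difference was -2.23 ± 0.28 log2 units (SE, adjusted p = 0.0177), while another Insig2 probe was at -0.30. Ugt1a10 went from 9.88 to 7.38 in wild type and from 7.79 to 7.38 in knockout. Its difference was 2.08 ± 0.29 (adjusted p = 0.0486). In both genes wild type on the normal diet was the group that stood apart. H4c1 did not pass (adjusted p = 0.0793), nor did Cyp2b10 at -1.54, Depp1 at -1.70 or Lcn2 at -0.34. The CL effects on these genes were therefore not shown to differ between genotypes.

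**Figure D4:**
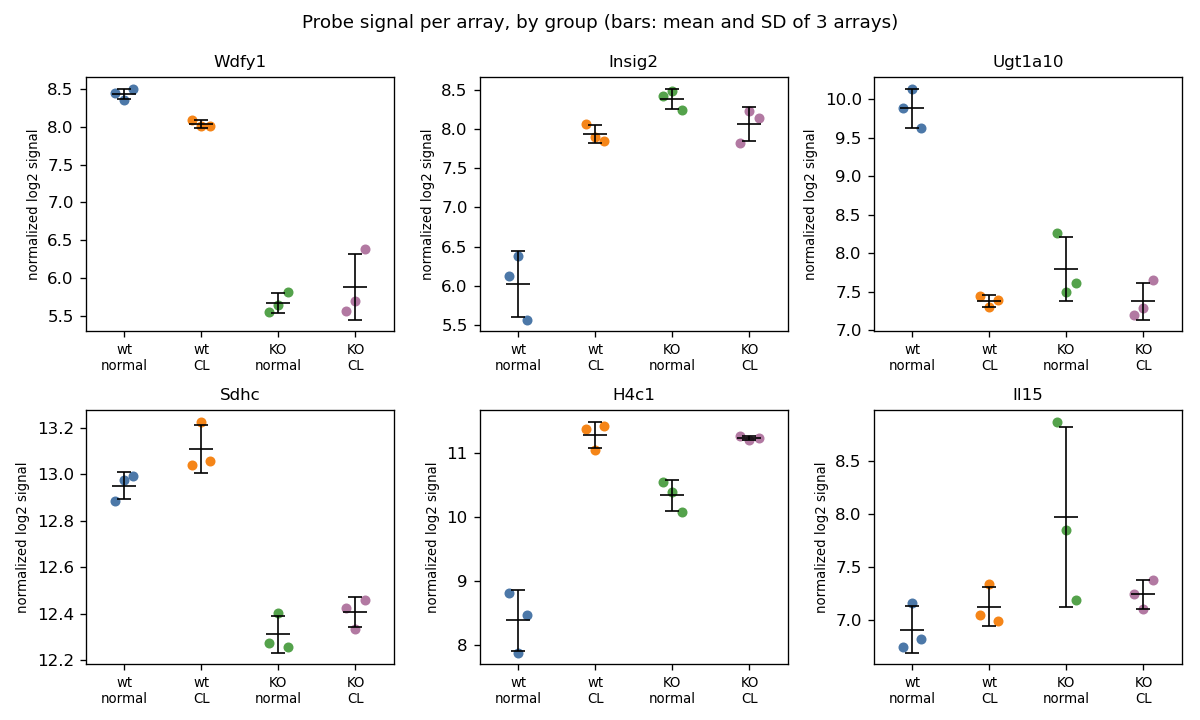
Normalized log2 signal of Wdfy1, Insig2, Ugt1a10, Sdhc, H4c1 and Il15 on each of the 12 arrays, by group; bars are the mean and SD of 3 arrays. Wdfy1 lies at 8.43 and 8.04 in wild type and at 5.67 and 5.88 in knockout, whereas Insig2 is lower in wild type on the normal diet, at 6.03, than in the other groups, at 7.94 to 8.38.

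As groups, macrophage markers differed in their CL effect, at a median of -0.59 in knockout and 0.17 in wild type, where the list did not pass (median difference -0.75, adjusted p = 1.29e-10; adjusted p = 0.237 with an estimated correlation), with 0 of 17 past the threshold, or 5 adjusted over the list alone. Lyz1 was at -1.28, Lyz2 at -1.50 and Gpnmb at -2.15. The mean macrophage score was 0.39 in knockout on the normal diet and -0.15 in knockout on CL. In wild type it was -0.26 on the normal diet and 0.02 on CL. The difference of the CL effect thus rests in part on the same knockout normal-diet arrays as the fall with CL in knockout. Lower differences were also found for fibroblast and extracellular matrix genes (median -0.26, adjusted p = 0.000121; adjusted p = 0.237 with an estimated correlation; Col1a1 at -0.82), circadian clock genes (median -0.41, adjusted p = 0.00201; adjusted p = 0.237 with an estimated correlation; Per1 at -1.66) and interferon-stimulated genes (median -0.17, adjusted p = 0.00581; adjusted p = 0.623 with an estimated correlation; Oasl2 at -0.75). In these lists 0 members passed, or 0, 1 and 0 adjusted over the list alone. Skeletal muscle markers differed by a median of -4.37 (adjusted p = 1.72e-17; adjusted p = 0.237 with an estimated correlation), with 0 past the threshold and 12 adjusted over the list alone.

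The calls on Insig2 and Ugt1a10 ended under 14 and 17 of 22 alternatives, with adjusted p of 0.00297 to 0.529 and of 0.00701 to 1.00, and leaving out any of the 12 arrays ended at least 1 of them. The counts were 0 without wild-type normal-diet array 1, wild-type CL array 1, 2 or 3, knockout normal-diet array 2 or knockout CL array 2 or 3, 1 without wild-type normal-diet array 3 or knockout CL array 1, and 0 with the replicate numbers as a block. The interferon list call ended without wild-type normal-diet array 1 or knockout CL array 2 or 3, with adjusted p of 1.52e-06 to 0.434 over its alternatives. Leaving out the 2 muscle-rich arrays or adding the muscle covariate ended the interferon and circadian calls (circadian 0.000292 to 0.428), and the covariate also ended the muscle call (0.78). The circadian median was -0.66 or -0.25 without wild-type CL array 1 or 3, and the matrix median -0.16 without wild-type normal-diet array 1 and -0.43 without knockout CL array 3. The interferon median was -0.01 or -0.52 without wild-type normal-diet array 1 or 3, -0.33 without wild-type CL array 2, -0.31 without knockout normal-diet array 1, and -0.38 or -0.10 without knockout CL array 1 or 3.

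Averaged over genotypes, the CL diet changed a broad set of genes, with 6 arrays on each side. Ckb rose by 2.26 ± 0.15 log2 units (SE, adjusted p = 4.14e-06), Gnmt by 2.22, Trp53inp1 by 2.34, Cyp2b10 by 3.39, Rgs2 by 2.10 and Rgs3 by 2.02, another Rgs3 probe being at 0.04. Hcar1 fell by 2.42 ± 0.15 (adjusted p = 3.75e-06), and the log2 changes of Igf1, Serpina3n, Lcn2 and Acot1 were -2.11, -2.36, -2.75 and -3.10. Il15ra rose 2.00-fold (log2 1.00, adjusted p = 0.00551) and all 3 of its other tested probes were higher as well, at 1.07, 1.28 and 0.80. Elovl3 rose 3.00-fold (log2 1.59 ± 0.43 SE, adjusted p = 0.0263), whereas Ucp1 was at -0.07 (adjusted p = 0.683).

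By group, endothelial markers rose (median 0.38, adjusted p = 0.00265; adjusted p = 0.5 with an estimated correlation), 6 of 15 higher and 1 lower, or 8 and 1 adjusted over the list alone, with Tie1 at 1.02 and Robo4 at 0.91. Chemokines and inflammatory mediators fell (median -0.68, adjusted p = 0.00286; adjusted p = 0.5 with an estimated correlation), 7 of 15 lower and 1 higher, or 9 and 1 adjusted over the list alone, among them Cxcl14 at -1.25 and the eosinophil chemokine Ccl11 at -0.69. Interferon-stimulated genes fell (median -0.33, adjusted p = 0.0217; adjusted p = 0.695 with an estimated correlation), 6 of 19 lower and 1 higher, or 9 and 2 adjusted over the list alone, among them Bst2 at -1.18, Irf7 at -0.90 and Usp18 at -1.10. Glycolysis and glucose uptake genes rose (median 0.26, adjusted p = 0.0207; adjusted p = 0.5 with an estimated correlation), 3 of 14 higher, or 4 and 1 lower adjusted over the list alone. These were Slc2a1 at 0.58, Pgam1 at 0.37 and Pgk1 at 0.48, with another Pgk1 probe at -0.22. Skeletal muscle markers fell on average (median -1.25, adjusted p = 0.0257 in camera, or 0.734 with an estimated correlation), with 0 of 14 past the threshold. This average covers opposite signs, with a median of 0.90 in wild type and -3.54 in knockout.

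Lists that did not pass in the averaged comparison nevertheless held single genes that did. The counts higher and lower were 2 and 1 of 17 brown fat and thermogenic genes (adjusted p of the list 0.886), 3 and 1 of 14 cAMP-responsive early genes (0.227), 4 and 3 of 15 lipolysis and lipid uptake genes (0.954), 4 and 2 of 19 fatty acid oxidation genes (0.165), 1 and 1 of 19 fatty acid and triglyceride synthesis genes (0.306), 2 and 0 of 22 oxidative phosphorylation genes (0.0868) and 1 and 2 of 7 white adipocyte genes (0.484). They were 3 and 7 of 15 unfolded protein response genes (0.151), 1 and 3 of 12 circadian genes (0.245), 1 and 2 of 17 macrophage markers (0.306), 4 and 2 of 17 matrix genes (0.886), 0 and 1 of 14 cell cycle genes (0.886), 1 and 0 of 8 T cell markers (0.306) and 1 and 0 of 7 Schwann and nerve markers (0.349). NK cell, B cell and erythroid markers had 0 in either direction (0.306, 0.697 and 0.306).

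In all, 2619 probes were called for the averaged diet effect, 1349 higher and 1270 lower, standing for 1876 named genes, 237 of the probes with a change of more than 2-fold. With median scaling 20.9% of 2027 calls were higher, against 51.5% here. Without the 2 muscle-rich arrays the count was 1664. Of 31 named genes past the threshold, 22 kept their call under all alternatives, other probes included, and those on Cyp2b10, Rgs3 and Oasl2 ended with another probe alone (0.28, 0.04 and -0.22). That on Pecam1 ended with median scaling (0.00346 to 0.174). That on Elovl3 ended under 9 of 23, including the omission of wild-type normal-diet array 2, wild-type CL array 1, knockout normal-diet array 3 or knockout CL array 1, with adjusted p of 0.00211 to 0.0989. Leaving out any array except knockout CL array 1 ended at least 1 of the calls on Slc2a1, Pgk1, Pgam1 and Usp18 (adjusted p 0.00267 to 0.863 over their alternatives). The interferon list call ended without wild-type normal-diet array 3, knockout normal-diet array 2 or knockout CL array 2 or 3 (0.000716 to 0.121), and the muscle list call without wild-type normal-diet array 2, wild-type CL array 1 or 2, knockout normal-diet array 2 or knockout CL array 3 (1.06e-06 to 0.933). The stricter filter ended the chemokine (0.000178 to 0.452), glycolysis (0.00543 to 0.115), interferon and muscle calls. Median scaling ended the last 3 of these, the authors' values the interferon and muscle calls, the lack of background correction or array weights the muscle call, and the muscle covariate the interferon call, while it reversed the muscle list. Without wild-type CL array 2 or 3 the muscle median was -0.67 or -1.91.

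Averaged over diets, 4 named genes were called between genotypes, all of them on chromosome 1 (0.21 expected, adjusted p = 0.000157, Fisher's exact test). Wdfy1 was 5.50-fold lower in knockout (log2 -2.46 ± 0.13 SE, adjusted p = 1.7e-06) and kept its call under 22 alternatives, while its other probe was at -0.23 and did not pass. Sdhc, another subunit of complex II, was 1.59-fold lower (log2 -0.67 ± 0.09 SE, adjusted p = 0.0107), at 12.31 and 12.40 in knockout against 12.95 and 13.11 in wild type. Insig2 was 2.36-fold higher (adjusted p = 0.00365) and Ugt1a10 2.06-fold lower (adjusted p = 0.0231), and for both the difference of the CL effect between genotypes also passed. On the CL diet alone they differed by 0.12 and -0.005 log2 units, so their averages rest on the normal diet.

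Macrophage markers were higher in knockout on average (median 0.22, adjusted p = 0.00031; adjusted p = 0.376 with an estimated correlation), as were interferon-stimulated genes (median 0.23, adjusted p = 0.00034; adjusted p = 0.541 with an estimated correlation). So were cell cycle genes (median 0.21, adjusted p = 0.000711; adjusted p = 0.376 with an estimated correlation) and matrix genes (median 0.17, adjusted p = 0.00191; adjusted p = 0.376 with an estimated correlation). Chemokines and B and plasma cell markers were higher too (medians 0.10 and 0.61, both with adjusted p = 0.0451; adjusted p = 0.603 and 0.376 with an estimated correlation). These averages cover unlike diets: on the CL diet the medians were -0.14 for macrophage markers, -0.02 for matrix genes, 0.07 for interferon-stimulated genes and -0.01 for chemokines, against 0.67, 0.39, 0.30 and 0.21 on the normal diet. In all 6 lists 0 members passed, over all probes or adjusted over the list alone. C1qa was at 0.63, Psmb8, an immunoproteasome subunit, at 0.49, Mcm5, a replication helicase subunit, at 0.41, Fn1 at 0.48, Icam1 at 0.39 and Cd79b at 0.75 log2 units. In total 6 probes were called, 2 higher and 4 lower, against 1007 at an unadjusted p under 0.05. There were 3 without knockout normal-diet array 3 and 3 with the replicate numbers as a block. The call on Sdhc ended without knockout normal-diet array 3 or knockout CL array 2, without the 2 muscle-rich arrays, with median scaling and with the replicate numbers as a block (adjusted p 3.95e-05 to 0.113 over 22 alternatives), and that on Insig2 with median scaling and without the 2 muscle-rich arrays (0.000346 to 0.0873). That on Ugt1a10 ended under 13 of 22, including the omission of any array except wild-type normal-diet array 3, knockout normal-diet array 1 and knockout CL array 3 (0.0033 to 0.173). Of the list calls, the interferon call ended without wild-type normal-diet array 1 (5.85e-09 to 0.0895) and the matrix call without knockout CL array 3 (1.14e-05 to 0.0523). The chemokine call ended without wild-type normal-diet array 1, wild-type CL array 1 or 2, knockout normal-diet array 1 or 3 or knockout CL array 3 (0.00217 to 0.609). The B cell call ended without wild-type normal-diet array 1 or 3, wild-type CL array 1 or 2, knockout normal-diet array 2 or 3 or knockout CL array 1 (0.00363 to 0.964). Both also ended with the authors' values, without background correction, with the stricter filter and with array weights, and the B cell call without the 2 muscle-rich arrays, with the muscle covariate and with chromosome 1 left out. Without knockout CL array 1 the B cell, cell cycle and interferon medians were 0.11, 0.14 and 0.10. The cell cycle median was 0.13 without knockout normal-diet array 3 and the macrophage median 0.10 without knockout normal-diet array 1. The chemokine median was 0.07 or 0.18 without wild-type normal-diet array 1 or 3, 0.06, 0.19 or 0.06 without knockout normal-diet array 1, 2 or 3, and 0.17, 0.16 or 0.05 without knockout CL array 1, 2 or 3.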

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

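The tests of chromosome 1 genes, of histone genes and of group differences in muscle markers were chosen after the results were seen. That of other muscle genes was chosen after the markers but before the values of those genes were seen, and the counts over other groupings of the arrays were planned before.

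By the test of the difference itself, limma called a CL effect that differed between genotypes for Insig2, by -2.23 log2 units, and for a pair of Ugt1a10 probes, by 2.14 and 2.08. The calls on both genes ended under most alternatives, and chance may account for their number. Among gene lists, the median difference was -0.75 for macrophage markers. It was -0.17 for interferon-stimulated genes, -0.26 for fibroblast and extracellular matrix genes and -0.41 for circadian clock genes, none of these calls holding with an estimated correlation. Skeletal muscle markers differed by a median of -4.37, a call that did not hold with an estimated correlation either.

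Insig2 and Ugt1a10 belong to a set of 9 chromosome 1 genes among the 21 named genes with a chromosome that differed between genotypes on the normal diet. The excess stayed under every setting of normalization or background tested, with a largest Fisher's exact p of 4.11e-05 over 3 settings, which argues against the processing as its cause. When genes were chosen without 1 array of each normal-diet group, the 3 to 6 chromosome 1 genes called differed more on the left-out arrays than on the CL diet. The gap was a median of 0.78 to 2.24 log2 units over the 9 choices (SD 0.50). The choices reuse the same arrays and largely the same genes, with Insig2, Ugt1a10 and Wdfy1 in each, so this SD does not measure the error of the gap. For these few genes on these arrays, the gaps argue against an effect of the genotype alike on both diets, without a measured error. For 8 of the 9 genes the wild-type CL mean lay nearer to the knockout mean (4 of the 5 called with only the arrays of the compared groups). That mean is no part of the contrast that chose them, although those arrays entered its variance. A difference in genetic background between the wild-type normal-diet mice and the other mice may account for these genes. Anything else that sets the wild-type normal-diet arrays apart gives the same nearness, so it does not single out that explanation. Of 39 histone genes, 20 were also lower on all 3 of those arrays than on the others. Wdfy1, lower in knockout on both diets, is outside the pattern of these 8 genes. So is Sdhc, a chromosome 1 gene that passed only in the average over diets, at 12.3 to 12.5 on the knockout arrays and 12.9 to 13.2 on the wild-type arrays. Strain, litter and harvest of the mice and wrong genotype labels stay open as untested.

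Of 39 measured histone genes, 20 were lower on all 3 wild-type normal-diet arrays than on the other 9 arrays. A technical difference of those arrays as a group could give this, and it cannot be told apart from the group itself because no batch is given. More dividing cells in the other groups were tested with cell cycle genes detected on all arrays, whose median change with CL in wild type was -0.38. Only 2 such genes were measured. The limits from resampling genes, -0.64 and -0.12, are then just the changes of these 2 genes and hold no spread between arrays. That explanation stays open as well. Near-identical sequences of the histone genes also leave open how many separate genes the 20 stand for.

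The skeletal muscle markers ranged by up to 4.37 log2 units between arrays of 1 group, more than the 3.06 between group means, so an effect of the genotype or the diet on them cannot be told apart from differences between samples with 3 arrays a group. Of 12 skeletal muscle genes outside the marker list, 7 were measured, 0 of them detected on all arrays (10 of the 14 markers were). On the array with the highest marker mean, all 7 were above the mean of the other arrays of its group, by 0.53 to 2.96 log2 units (median 2.31), while 46.1% of all genes were. The raw signal of Acta1 was 15846 on that array against 4348 on the others of its group, and that of Myl1 was 14714 against 6631. Muscle tissue in some samples is a candidate explanation, muscle genes expressed within the fat are not excluded, and the macrophage, matrix and clock differences were measured on the same arrays.

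Other groupings of the same arrays were counted for each comparison. For the CL diet averaged over genotypes, 1 of 100 groupings gave as many calls, the real one with 2619 against 75 at most in the others. A share of 1 in 100 is the lowest that this sample of groupings can give, so chance is unlikely rather than excluded. The count also treats the arrays as exchangeable, although no animal or batch is given for them. For genotype averaged over diets 5 of 100 gave as many calls (6 calls, 10 at most in the others). For the difference of the CL effect 9 of 100 did (3 calls, 12 at most), so chance may account for either count. With 3 arrays against 3 there are only 10 groupings, too few for a share under 0.05. There the real counts and the highest of the others were 827 and 0 for CL in wild type, 529 and 0 for CL in knockout, 33 and 1 for genotype on the normal diet, and 2 and 2 for genotype on the CL diet. At least as many calls came from 1, 1, 1 and 2 of those groupings.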

How the results depend on the processing

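The fit without the 2 muscle-rich arrays, the muscle covariate and the omission of chromosome 1 were chosen after seeing the data; the other alternatives were planned. Of 103 calls on named genes, 42 held under all alternatives, other probes included, 40 ended with some array left out and 61 under some other setting. Of 37 list calls, 19 ended with some array left out and all 37 with the estimated correlation. The cause was not tested except where stated. Chip as a block was not run. Leaving out an array leaves 2 in its group, whose spread is then pooled with the other groups.

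Counts of probes called moved by over 1.5 times as follows. Genotype on the normal diet gave 18 with the authors' values and 16 without background correction, and genotype on the CL diet 4 and 4. Median scaling gave 167 for CL in knockout, 12 for genotype on the normal diet, 0 for the difference of the CL effect and 2 for genotype averaged over diets. With it the median of all probes was -0.14 for CL in wild type and -0.11 for the averaged CL effect, each -0.01 with quantile normalization, and 21.2%, 23.4% and 20.9% of the calls for CL in wild type, in knockout and on average were higher, against 51.8%, 55.6% and 51.5% with quantile normalization. Without a filter, genotype on the normal diet gave 11 and the difference of the CL effect 0, and with the stricter filter genotype averaged over diets gave 12. With the replicate number as a block the difference of the CL effect gave 0 and genotype averaged over diets 3. Array weights gave 1569 for CL in wild type, 1127 for CL in knockout, 6 for the difference and 15 for averaged genotype. Trended and robust moderation gave 4 for genotype on CL, 7 for the difference and 16 for averaged genotype. With only the arrays of the compared groups, and so fewer residual degrees of freedom, CL in knockout gave 131, genotype on the normal diet 12 and genotype on CL 0. Without the 2 muscle-rich arrays CL in wild type gave 287, genotype on the normal diet 8, the difference 0, averaged CL 1664 and averaged genotype 2. The muscle covariate gave 33 for CL in knockout, 8 for genotype on the normal diet and 0 for the difference. With chromosome 1 left out, and so fewer genes tested, genotype gave 10 on the normal diet, 1 on CL and 1 on average, and the difference 0.

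With each array left out in turn, the counts were 273 to 813 for CL in wild type, 163 to 372 for CL in knockout, 11 to 32 for genotype on the normal diet, 2 to 2 on CL, 0 to 3 for the difference, 1835 to 2583 for averaged CL and 3 to 7 for averaged genotype. Directions that reversed were those of the B cell list for genotype on CL with the stricter filter (-0.16), the muscle list for averaged CL with the muscle covariate (by the camera test, at a median of -0.047), another Sdhb probe for CL in knockout (-0.021) and another Pgk1 probe for averaged CL (-0.22).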

Other observations

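The glucocorticoid test below rests on members whose values had not been seen when its prediction was written, though the idea came from other members seen before, and the omission of single arrays was chosen after the result was seen.

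Several genes that respond to glucocorticoids, most of them outside the fixed lists, had higher means in wild type on the CL diet. They were noticed in Tsc22d3, Fkbp5, Per1, Zbtb16 and Ddit4, at 1.82, 1.38, 2.03, 1.98 and 2.09 log2 units with CL in wild type and at 0.29, -0.03, 0.37, 0.67 and 0.58 in knockout. Fkbp5 was at 5.01 on wild-type CL array 1, below all 3 wild-type normal-diet arrays, so its value rests on arrays 2 and 3 (7.74 and 7.99). Cdkn1a, Lcn2, Dusp1 and Nfkbia had also been seen and were set aside, at 1.84, -2.58, 0.51 and 0.69 in wild type and 1.16, -2.93, 1.71 and 0.35 in knockout. Lcn2 and Dusp1 run against the pattern. The hypothesis was tested on 9 unseen genes, Sgk1, Klf9, Errfi1, Cebpd, Mt1, Mt2, Bcl6, Tat and Usp2, of which 8 were measured. They were read on the same 12 arrays as the genes that gave the idea, so they are not new samples. Camera sets them against other genes, and its p does not test whether the pattern recurs in other mice. With CL in wild type their mean change was 0.67 ± 0.12 (SE over arrays), with 7 of 8 higher and 1 past the threshold. The camera p was 0.00346, a call that did not hold with an estimated correlation (0.0854). In knockout the mean change was -0.04 ± 0.25.

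On the CL diet the mean of these 8 genes was -0.56 ± 0.26 in knockout relative to wild type (SE over arrays), 7 of 8 lower, with a camera p of 1.71e-05, or 0.0203 with an estimated correlation. Errfi1 was at -0.85, Sgk1 at -0.63, Klf9 at -0.41 and Mt2 at -1.21, while Cebpd was at 0.21, and 0 of the 8 passed singly. The mean difference of the CL effect was -0.71 ± 0.28, with a p of 0.0272 with an estimated correlation, which rose to 0.0503, 0.0574 and 0.0502 without wild-type normal-diet array 2 or knockout normal-diet array 1 or 3.

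Much of the size of these differences came from knockout CL array 1, where the mean of the 8 genes was 8.93, against 9.65 and 9.67 on the other 2 arrays of its group and 9.78 to 10.07 on the wild-type CL arrays. Without it the difference on the CL diet was -0.31 ± 0.09 (p = 0.0325 with an estimated correlation in camera), the difference of the CL effect -0.46 ± 0.13 and the CL effect in knockout 0.20 ± 0.04. The same array stood apart in B cell (2.08) and T cell (1.08) marker scores, so its composition stays open as a source of part of the difference. The direction of the difference on the CL diet (-0.56 with all arrays) is consistent with a higher glucocorticoid response of the wild-type mice on that diet, while its size rests on that array. The time of harvest stays open, since clock genes differed too (median difference of the CL effect -0.41) and Per1 belongs to both sets. That clock list call did not hold with an estimated correlation or with the muscle covariate. Hormone levels, handling and the muscle content of the arrays were not tested.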
